A study of Homo sapiens with 19 samples.

How the data were processed

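Gene expression was measured in SKBR3 cells, a human breast cancer line with an amplified ERBB2 gene, on 19 Affymetrix arrays with 54675 probe sets each. Per the labels, cells were exposed to 60 nM epirubicin, an anthracycline that traps topoisomerase II on DNA, over 3 days, or were kept in 1% oxygen over 7 days. Cells were then separated by flow sorting on surface CD44, a hyaluronan receptor, into CD44lo and CD44hi fractions. The labels give 3 untreated samples and 4 samples in each of the other 4 groups, and they name no sort for the untreated samples. The samples are called biological replicates, but nothing states that they were separate cultures, so the p-values measure the spread between these samples and no more. Biotin-labelled RNA was prepared from 200 ng of total RNA per sample.

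The deposited values are linear signal intensity per probe set, made by the authors with MAS5, the tool named in the submitters' processing notes. Its version and settings are not stated. Every array had a mean of 100.0 after removal of the lowest and highest 2% of values, so the arrays had been scaled to a common level, and no further scaling was applied. No detection calls were used here. Of the probe sets, 62 were controls of the array maker, 41091 named exactly 1 gene, 1801 named several genes and 11721 named none. The probe sets with 1 gene covered 19775 genes. Each gene was represented by the probe set with the highest mean over all arrays, and a probe set whose type admits probes shared with other genes was used only where a gene had no other. Probe sets with several genes or none were left out of the comparisons.

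Signals were analysed as log2(signal + 4.2), where 4.2 is the 25th percentile of the table. Fold changes are given on this scale and understate changes of genes with signals near or under the offset. A gene was tested when at least 3 arrays reached 16.9, the median of the table, which left 12917 genes. The 19 arrays were fitted together with 5 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a variance trend. The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene is called higher or lower at an adjusted p under 0.05. The 7 comparisons were CD44hi against CD44lo after each treatment, each of the 4 sorted groups against untreated, and the difference between the CD44 effects of the treatments. Values after ± are standard errors for log2 fold changes and SD for mean signals.

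The 17 gene lists, with 377 members in all, cover the hypoxia response, p53 targets, mitosis, DNA replication, the type I interferon response, NF-kB and inflammatory cytokines, mesenchymal genes, epithelial and luminal genes, basal genes, stem cell associated genes, ER stress and the amino acid response, cholesterol synthesis, antigen presentation, oxidative phosphorylation, the ERBB2 amplicon, immune cell markers, and stromal and endothelial markers. Each was tested in each comparison, 119 tests in all, with limma's camera at an inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Camera with a correlation estimated for each list was the alternative. Of the 48 list tests that passed, 6 held with the estimated correlation. These were the basal list in CD44hi against CD44lo after epirubicin and in both hypoxia groups against untreated, and the interferon, NF-kB and antigen presentation lists in CD44hi after epirubicin against untreated. A list's median, mean and test differed in sign in 13 of the 119 tests, and 0 of those passed. The number of called members is also given with p adjusted over the list alone. Members below the filter on signal, or without a probe set of their own, were not tested. Of the mesenchymal list, VIM, ZEB1, ZEB2, SNAI2, TWIST1, TWIST2 and SPARC were among those below the filter. Of the stromal and endothelial list only PECAM1, CDH5 and KDR were tested. These genes are named here outside the rule given next.

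Genes were named by a fixed rule. CD44, CD24 and ERBB2 are always named. Of each list that passed, or that had at least 3 called members, up to 4 called members with the largest change could be named. The 8 genes with the largest rise and the 8 with the largest fall, among called genes whose groups did not overlap, could be named too. Genes named outside this rule are marked where they appear. The groups, comparisons, tests, lists, naming rule and alternative settings were chosen before the data were examined.

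CD44, CD24 and ERBB2 were also compared as single values by two-sided exact permutation tests, for which the smallest possible p is 0.0286 with 4 arrays against 4 or against 3, and adjusted over their 18 tests. The overlap of 2 comparisons was tested with Fisher's exact test and with correlations across genes, which are not independent replicates. Treated groups share the 3 untreated arrays, so 50 simulated sets of unchanged groups gave the covariance that the shared arrays produce alone. Whether equal replicate numbers pair the CD44lo and CD44hi samples was checked from correlations of the arrays after removal of group means. After epirubicin, every pair of equal number correlated (r = 0.376, 0.545, 0.114 and 0.459, across genes), and 7 of 8 arrays correlated best with the array of their own number. After hypoxia the pairs correlated at r = -0.04, 0.634, 0.279 and 0.541, and 6 of 8 arrays correlated best with the array of their own number. Not every pair there exceeded 0.1, the bound used for pairing. Gene calls with the number as a block are given after both treatments, with less certain pairing after hypoxia. List tests with the block are given beside the comparison after epirubicin alone.

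The alternative settings were an offset of 0 with a floor of 0.6, a doubled offset, no filter, a stricter filter of 97.7, quantile normalization, the mean of all probe sets of a gene, no variance trend, a fit of the compared groups alone, the replicate number as a block, and leaving out each array. Added after the data had been seen were fits without the epirubicin arrays numbered 4, without the 4 sorted arrays numbered 2, and with the level of the hybridisation controls as a covariate, the list tests without each array, exact permutations within pairs of equal number, and 3 further gene lists. The method was tested on simulated data with 12917 genes. In the comparison of 4 arrays with 4, it recovered 58.8% of genes changed by 1 log2 unit, 93.8% of those changed by 2 and 100% of those changed by 3, with 16 false among 178 calls. The simulated noise was independent between arrays, with no structure by replicate number and the same spread in every group. The share recovered in the real data may thus be lower. Between CD44hi and CD44lo cells after epirubicin, CD44 differed by 2.57 log2 units and was not called without the block. The number of arrays limits the precision of every comparison. Probe sets of gene families with nearly identical sequences, such as actins, HLA genes, metallothioneins, PSG genes and histones, can pick up related transcripts, so values of single members are uncertain.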

Results

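The data describe SKBR3 breast cancer cells left untreated (n = 3 arrays), and CD44lo and CD44hi cells sorted after epirubicin or after low oxygen (n = 4 arrays in each of 4 groups). The comparisons ask how expression differs from untreated cells after each treatment, and whether CD44lo and CD44hi cells differ after each. The labels name no sort for the untreated cells, so a comparison with untreated cells does not separate the treatment from the sorting. Between 6451 and 6860 genes per array had a signal above 100. Arrays of the same group correlated at r = 0.920 to 0.985 across genes.

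The first principal component, with 40.2% of the variance, placed untreated arrays at -43.9 to -42.7, epirubicin arrays at -35.0 to -0.70 and hypoxia arrays at 8.70 to 63.4. The hypoxia arrays numbered 2 lay closest to the untreated arrays, at 8.70 for CD44lo and 22.8 for CD44hi. The epirubicin arrays numbered 4 had the highest ratios of 3' to 5' signal for ACTB, a measure of RNA quality, at 1.71 for CD44lo and 1.85 for CD44hi, against a mean of 1.24 ± 0.03 in untreated cells. Bacterial hybridisation controls averaged 1336 ± 121 on untreated arrays, 2097 ± 580 in CD44lo and 2889.6 ± 1177 in CD44hi cells after epirubicin, and 1669 ± 255 and 1717 ± 217 in the hypoxia groups. Of the variance of these controls on the log2 scale, 46.8% lay between the groups. In two-sided exact permutation tests of the controls and of the ACTB ratio between compared groups, p ranged from 0.0571 to 0.971, with 0.0286 the smallest possible, which does not show that the levels were equal.

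The sort marker itself followed the sort. CD44 transcript averaged 648 ± 476 in CD44hi and 88.0 ± 33.2 in CD44lo cells after epirubicin, a 5.94-fold difference on the log2 scale with its offset (log2 2.57 ± 0.65). After hypoxia it averaged 1042 ± 481 in CD44hi and 205 ± 194 in CD44lo cells, 7.46-fold apart (log2 2.90 ± 0.65). Untreated cells had 66.1 ± 13.2, so that CD44hi cells lay 7.53-fold above them after epirubicin and 13.8-fold after hypoxia. In these 4 contrasts every CD44hi array exceeded every array of the other group, with a two-sided exact permutation p of 0.0286, the smallest possible, and 0.129 after adjustment over 18 tests. In the fit across all genes CD44 was called against untreated (adjusted p = 0.0153 after epirubicin and 0.000466 after hypoxia). It was not called there between CD44hi and CD44lo (adjusted p = 1.00 and 0.385). With the replicate number as a block it was called between them after epirubicin (adjusted p = 0.0115) and after hypoxia (0.00287). After hypoxia not every pair of equal number correlated. The call against untreated after epirubicin ended without untreated array 1, untreated array 2 or CD44hi array 4, without the epirubicin arrays numbered 4, and with the hybridisation controls as a covariate.

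**Figure D1:**
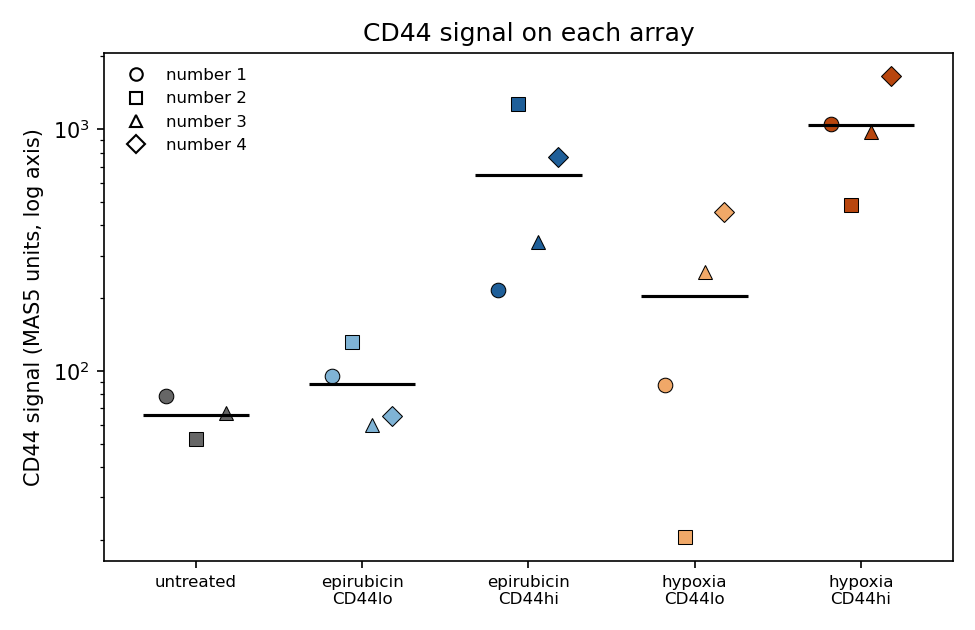
CD44 signal in MAS5 units on a log axis for each array, by group, with a symbol for the replicate number and a bar at the group mean. All CD44hi arrays lie above all CD44lo arrays of the same treatment, and CD44lo arrays after hypoxia range from 20.5 to 456.

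CD24, a surface glycoprotein often read together with CD44, averaged 3792 ± 553 in untreated cells and was higher in CD44hi cells after epirubicin (1.60-fold, log2 0.67 ± 0.20, adjusted p = 0.0451), a call that ended when any array but CD44hi array 2 was left out, and also without the filter, with quantile normalization, with the mean of all probe sets, without the variance trend, in a fit of the compared groups alone, without the epirubicin arrays numbered 4 and with the hybridisation controls as a covariate. It was not called in any other comparison. ERBB2, the receptor amplified in this line, was not called in any comparison, with mean signals from 2933 ± 442 in CD44lo cells after hypoxia to 3661 ± 468 in CD44lo cells after epirubicin. The 12 genes of the ERBB2 amplicon list held 0 called members in each comparison, and none with p adjusted over the list alone. The adjusted p of that list ranged from 0.316 in CD44hi cells after hypoxia against untreated to 0.987 between CD44hi and CD44lo after epirubicin.

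CD44lo cells sorted after 7 days of low oxygen were compared with untreated cells. They had higher levels of genes of the hypoxia and basal lists, and lower levels of genes of the mitosis and DNA replication lists; with an estimated correlation between genes only the basal list passed. EGLN3, an oxygen-dependent prolyl hydroxylase, rose 20.2-fold (log2 4.34 ± 0.32) and ADM, which encodes adrenomedullin, rose 11.8-fold (3.56 ± 0.45). SLC2A3, a glucose transporter, rose 33.4-fold (5.06 ± 0.63), and CXCR4 and ACKR3, receptors of the chemokine CXCL12, rose 26.9-fold (4.75 ± 0.40) and 28.5-fold (4.83 ± 0.60). The largest rises were those of ACTA1, an actin of skeletal muscle (60.2-fold, 5.91 ± 0.46), and MYL9, a myosin light chain (51.2-fold, 5.68 ± 0.41). Adjusted p for these genes was 3.43e-08 to 1.95e-05.

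In this comparison 2899 of 12917 genes were called, 1386 higher and 1513 lower, and 1514 of them changed at least 2-fold. The count was 1628 without untreated array 1, 1808 without untreated array 2 and 1894 without CD44lo array 4. Of 70 named calls, 58 held whichever array was left out.

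Of the 24 measured genes of the hypoxia list, 21 rose in CD44lo cells (22 adjusted over the list alone), with a median log2 change of 1.49 (adjusted p = 4.72e-19, and adjusted p = 0.0972 with an estimated correlation). Other risers were ENO2, a glycolytic enolase (20.4-fold, log2 4.35 ± 0.76), and BHLHE40, a transcriptional repressor (8.28-fold, 3.05 ± 0.41). The list mean on array 2 was 1.05 above untreated against 2.09 to 2.26 on the other arrays, and ADM was also lowest on array 2. All 25 mitosis genes fell (25 adjusted over the list alone; median -2.68, adjusted p = 8.77e-21, and adjusted p = 0.151 with an estimated correlation). DLGAP5 and KIF20A, which act on the spindle, were 10.8-fold (log2 -3.44 ± 0.59) and 10.5-fold lower (-3.40 ± 0.57), and PTTG1, which encodes securin, was 14.4-fold lower (-3.85 ± 0.63). Of 24 DNA replication genes, 23 fell (24 adjusted over the list alone; median -1.71, adjusted p = 1.41e-14, and adjusted p = 0.156 with an estimated correlation), among them TYMS, the thymidylate synthase (5.06-fold lower, -2.34 ± 0.37), and RRM2, a ribonucleotide reductase subunit (5.22-fold lower, -2.38 ± 0.45). CDKN1A, the inhibitor of cyclin-dependent kinases, rose 6.55-fold (2.71 ± 0.43), while the p53 target list as a whole had 5 members higher and 1 lower of 20 (6 and 1 adjusted over the list alone; adjusted p = 0.537).

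Genes of the basal list also rose in CD44lo cells after hypoxia, 9 of 11 over all genes and 9 adjusted over the list alone (median 1.93, adjusted p = 1.95e-08, and adjusted p = 0.024 with an estimated correlation). CAV1, the main coat protein of caveolae, rose 24.1-fold (log2 4.59 ± 0.37), LAMB3, a laminin chain, 10.2-fold (3.35 ± 0.36), and KRT5, a basal keratin, 11.1-fold (3.48 ± 0.52). The mesenchymal list had 5 of 11 members higher (7 adjusted over the list alone; median 1.06, adjusted p = 5.09e-05, and adjusted p = 0.151 with an estimated correlation). FN1, which encodes fibronectin, rose 12.4-fold (3.63 ± 0.46) and ACTA2, the smooth muscle actin, 17.7-fold (4.14 ± 0.39). Other members, among them VIM, ZEB1 and SNAI2 (named outside the rule), lay below the filter and were not tested. The stem cell associated list had 6 of 19 members higher over all genes and over the list alone (median 0.38, adjusted p = 0.00707, and adjusted p = 0.156 with an estimated correlation), with JAG1, a Notch ligand, 12.3-fold (3.62 ± 0.43) and HEY1, a Notch target, 6.61-fold higher (2.72 ± 0.25). The median of that list was 0.23 without CD44lo array 4. The epithelial and luminal list had 3 higher and 1 lower of 24 over all genes and over the list alone (adjusted p = 0.355), with DSP, a desmosomal protein, 2.92-fold higher (1.54 ± 0.18) and the transcription factor XBP1 3.12-fold lower (-1.64 ± 0.39). XBP1 was not called when all its probe sets were averaged.

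Among the inflammatory genes in CD44lo cells after hypoxia, 7 of 17 on the NF-kB list rose (8 adjusted over the list alone; median 0.90, adjusted p = 9.76e-05, and adjusted p = 0.238 with an estimated correlation), among them the chemokine CCL2 (5.54-fold, log2 2.47 ± 0.55). The interferon list had 6 higher and 1 lower of 18 (7 and 3 adjusted over the list alone; adjusted p = 0.0405, and adjusted p = 0.358 with an estimated correlation). Of 24 oxidative phosphorylation genes, 14 fell (16 adjusted over the list alone; median -0.55, adjusted p = 4.55e-06, and adjusted p = 0.251 with an estimated correlation), such as UQCRC2 of respiratory complex III (2.14-fold lower, -1.10 ± 0.27). The cholesterol list had 6 members lower and 1 higher of 13 (7 and 1 adjusted over the list alone; median -0.66, adjusted p = 0.0352, and adjusted p = 0.376 with an estimated correlation). EBP, a sterol isomerase, was 2.52-fold lower (-1.33 ± 0.27), whereas SC5D, a sterol desaturase, was 2.50-fold higher (1.32 ± 0.19). The interferon and cholesterol lists did not pass without untreated array 1 (adjusted p = 0.0678 and 0.183), untreated array 2 (0.0595 and 0.0703) or CD44lo array 3 (0.0892 and 0.0523). The ER stress list had 5 higher and 4 lower of 20 over all genes and over the list alone (adjusted p = 0.867), and the antigen presentation list 3 higher and 1 lower of 16 (the same counts over the list alone; adjusted p = 0.507). Markers of stromal and endothelial cells were called for 2 of 3 measured genes (2 over the list alone; adjusted p = 0.0576), and immune markers for 0 of 5 (0 over the list alone; adjusted p = 0.223).

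CD44hi cells after hypoxia, also compared with untreated cells, had the same 4 lists changed in the same directions, and with an estimated correlation again only the basal list passed. ACTA1 rose 196-fold (log2 7.61 ± 0.46), from a mean signal of 7.13 ± 0.60 to 2257 ± 529, and MYL9 rose 102-fold (6.67 ± 0.41). INHBA, which encodes the activin A subunit, rose 116-fold (6.86 ± 1.00), and IGFBP3, a binding protein for insulin-like growth factors, rose 96.8-fold (6.60 ± 0.42). CAV1 reached a mean signal of 2438 ± 519 against 53.6 ± 29.9, a 45.0-fold rise (5.49 ± 0.37), and SPRR3, a protein of cornifying epithelium with an untreated signal of 0.70 ± 0.44, rose 45.2-fold (5.50 ± 0.79). SCGB2A2, the mammaglobin of luminal breast cells, was 17.9-fold lower (-4.16 ± 0.64).

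Here 3467 genes were called, 1653 higher and 1814 lower, and 1940 changed at least 2-fold. Of 70 named calls, 66 held whichever array was left out.

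All 25 mitosis genes fell in CD44hi cells after hypoxia (25 adjusted over the list alone; median -2.81, adjusted p = 4.97e-19, and adjusted p = 0.131 with an estimated correlation), as did 22 of 24 DNA replication genes (22 adjusted over the list alone; median -1.48, adjusted p = 5.5e-11, and adjusted p = 0.199 with an estimated correlation). TPX2, a spindle assembly factor, was 8.85-fold lower (log2 -3.15 ± 0.47) and UHRF1, which recruits the maintenance DNA methyltransferase, 4.67-fold lower (-2.22 ± 0.35). The hypoxia list had 21 of 24 members higher (22 adjusted over the list alone; median 1.45, adjusted p = 3.62e-16, and adjusted p = 0.103 with an estimated correlation), and its mean on array 2 was 1.14 against 2.00 to 2.15 on the other arrays. CDKN1A rose 13.1-fold (3.72 ± 0.43) and GADD45A, a stress-inducible growth arrest gene, 3.97-fold (1.99 ± 0.33), within a p53 target list with 5 higher and 1 lower of 20 (5 and 3 adjusted over the list alone; adjusted p = 0.126). Oxidative phosphorylation genes fell for 12 of 24 (13 adjusted over the list alone; median -0.54, adjusted p = 9.7e-06, and adjusted p = 0.255 with an estimated correlation). Of the cholesterol list, 6 of 13 were lower and 1 higher (7 and 1 adjusted over the list alone; median -0.72, adjusted p = 0.0141, and adjusted p = 0.332 with an estimated correlation). INSIG1, a regulator of sterol sensing, was 5.46-fold lower (-2.45 ± 0.50), and SC5D was 2.54-fold higher (1.35 ± 0.19). The cholesterol list did not pass without untreated array 1 (adjusted p = 0.0873).

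The basal list had 10 of 11 members higher in CD44hi cells after hypoxia over all genes and over the list alone (median 3.18, adjusted p = 1.08e-10, and adjusted p = 0.00829 with an estimated correlation), among them LAMB3 (17.6-fold, log2 4.13 ± 0.36) and KRT5 (13.5-fold, 3.75 ± 0.52). The mesenchymal list had 8 of 11 measured members higher over all genes and over the list alone (adjusted p = 2.44e-06, and adjusted p = 0.103 with an estimated correlation). Its members below the filter, such as VIM, ZEB1 and SNAI2 (named outside the rule), do not enter this count. MMP2, a matrix metalloproteinase, rose 12.1-fold (3.60 ± 0.53) and ACTA2 48.8-fold (5.61 ± 0.39), with ACTA2 highest on array 2. Epithelial and luminal genes went both ways, 4 higher and 6 lower of 24 (5 and 7 adjusted over the list alone; adjusted p = 0.769). SPDEF, a luminal transcription factor, was 7.74-fold lower (-2.95 ± 0.67). The stem cell associated list had 7 higher and 2 lower of 19 over all genes and over the list alone (median 0.21, adjusted p = 0.0067, and adjusted p = 0.131 with an estimated correlation), with JAG1 20.5-fold (4.36 ± 0.43) and SOX9 7.56-fold higher (2.92 ± 0.36). The median of that list was 0.46 without untreated array 2, 0.36 without untreated array 3, 0.34 without CD44hi array 2 and 0.45 without CD44hi array 3.

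NF-kB and cytokine genes were called higher for 13 of 17 in CD44hi cells after hypoxia (13 adjusted over the list alone; median 1.53, adjusted p = 1.42e-07, and adjusted p = 0.131 with an estimated correlation). The chemokines CCL2 and CCL5 rose 14.9-fold (log2 3.90 ± 0.55) and 12.7-fold (3.66 ± 0.66), and TRAF1, an adaptor of TNF receptors, 10.5-fold (3.39 ± 0.48). The interferon list had 9 higher and 3 lower of 18 (11 and 3 adjusted over the list alone; median 0.87, adjusted p = 0.00898, and adjusted p = 0.255 with an estimated correlation), with ISG15, a ubiquitin-like protein, 5.51-fold higher (2.46 ± 0.58). The lists of antigen presentation (4 higher and 1 lower of 16), ER stress (4 higher and 2 lower of 20), immune markers (2 higher of 5) and stromal and endothelial markers (1 higher of 3) did not pass, with adjusted p of 0.126, 0.415, 0.0908 and 0.243. Over each list alone these counts were 4 and 1, 5 and 3, 3 and 0, and 1 and 0.

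**Figure D2:**
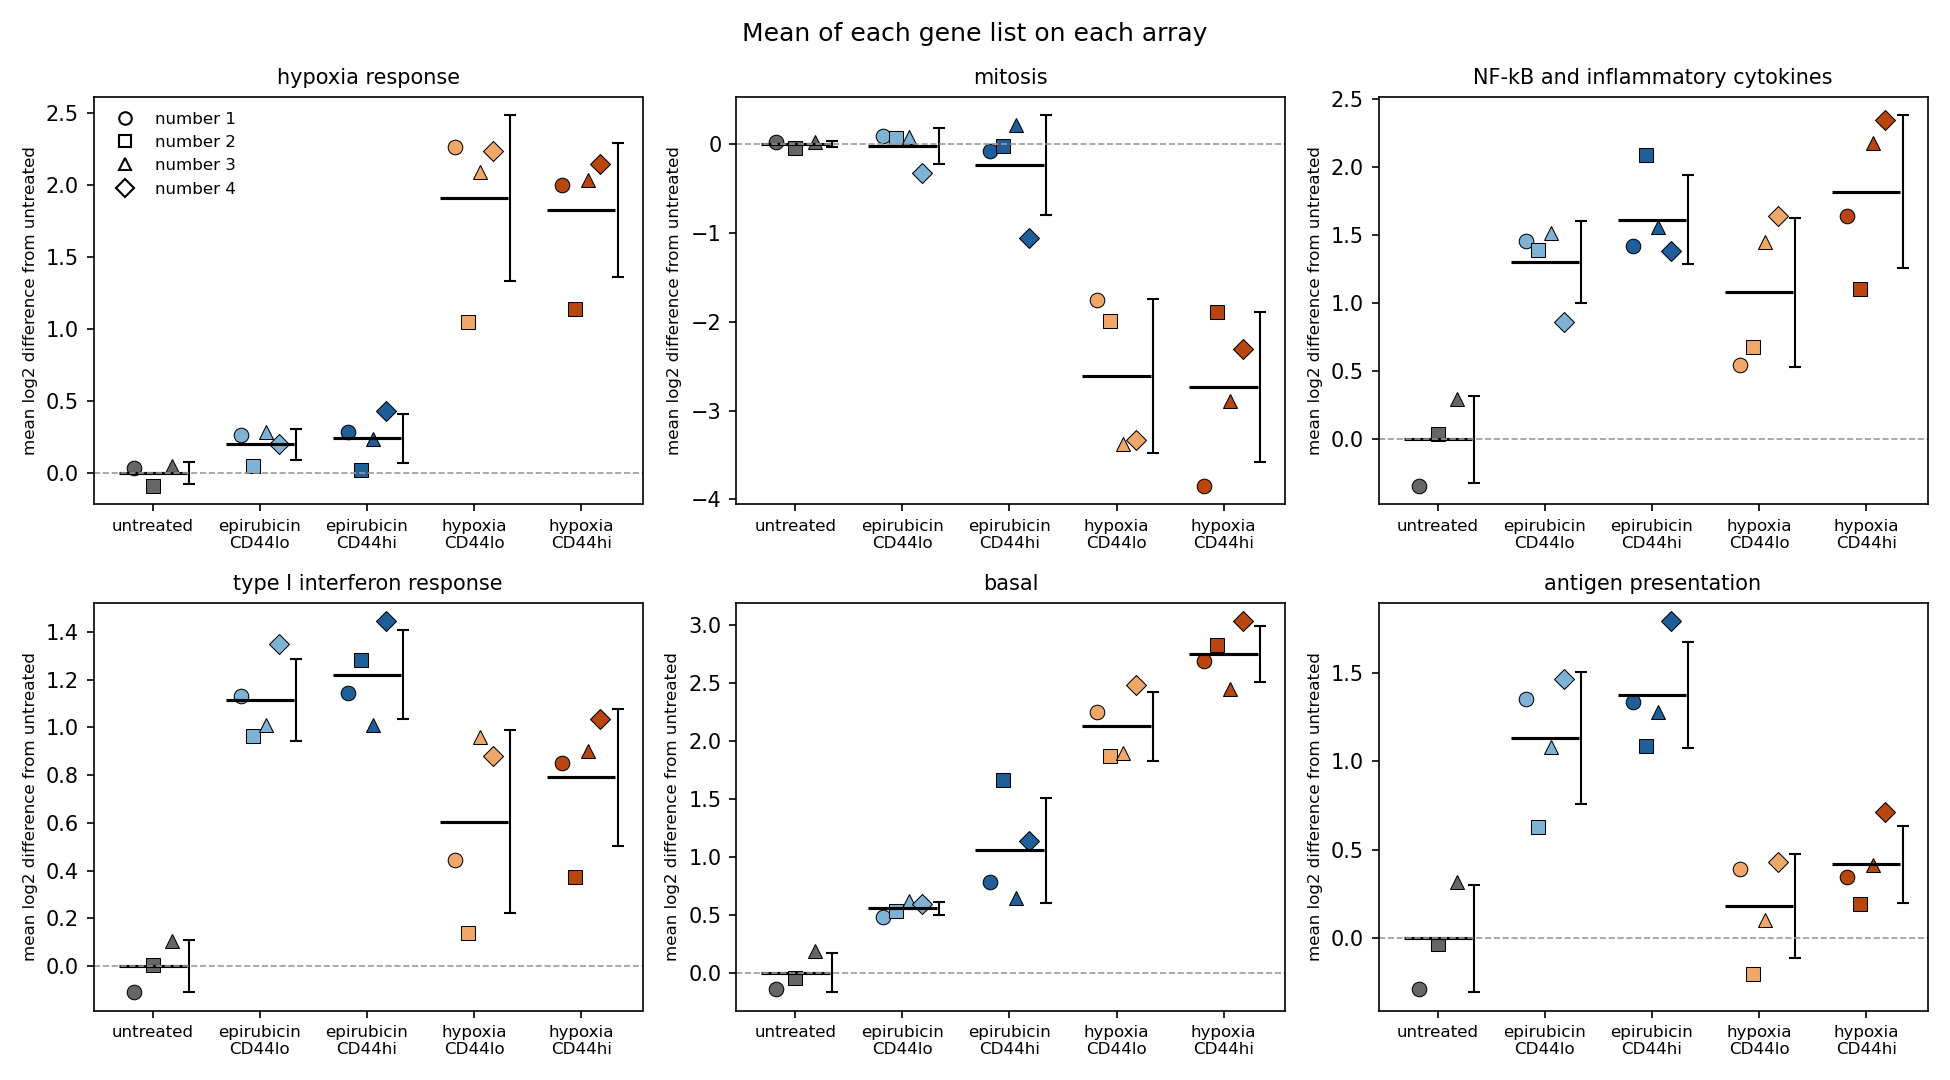
Mean log2 difference from the untreated mean over the measured genes of 6 lists, for each array, with a symbol for the replicate number, a bar at the group mean and an error bar of 1 SD. The hypoxia list lies between 1.05 and 2.26 on the 8 hypoxia arrays, lowest on the arrays numbered 2, and the mitosis list is lower on these 8 arrays than on any other array.

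CD44lo cells after 3 days of epirubicin were compared with untreated cells. They had higher levels of genes of the antigen presentation, interferon, NF-kB and ER stress lists, none of which passed with an estimated correlation. SERPINA3, a protease inhibitor, rose by 3.91 ± 0.47 on the log2 scale, from a signal of 4.67 ± 3.98 to 123 ± 26.1, and LCN2, an iron-siderophore binding lipocalin, rose 10.8-fold (3.43 ± 0.55), from 190 ± 81.5 to 2035 ± 525. GDF15, a stress-induced cytokine and p53 target, rose 14.9-fold (3.89 ± 0.63), and STEAP4, a metalloreductase, rose 8.86-fold (3.15 ± 0.53). LBP, which binds bacterial lipopolysaccharide, rose 13.1-fold (3.71 ± 0.57) from an untreated signal of 1.77 ± 1.30. Adjusted p for these 5 genes was 0.000225 to 0.00322, and each kept its call whichever array was left out.

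In this comparison 360 genes were called, 290 higher and 70 lower, and 248 changed at least 2-fold. The count fell to 66 without untreated array 1, 87 without untreated array 2, and 173, 159 and 180 without CD44lo arrays 1, 3 and 4. It was 199 without the epirubicin arrays numbered 4, 898 without the sorted arrays numbered 2, 1186 in a fit of the compared groups alone, and 103 with the hybridisation controls as a covariate, in which the median size of change of the 360 genes went from 1.20 to 1.05 and their median standard error from 0.27 to 0.29. Of 34 named calls, 11 held whichever array was left out.

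Antigen presentation genes were called higher for 7 of 16 in CD44lo cells after epirubicin, with all 16 changes positive (13 adjusted over the list alone; median 1.15, adjusted p = 2.69e-11, and adjusted p = 0.0741 with an estimated correlation). PSMB9 and PSMB8, subunits of the immunoproteasome, rose 6.86-fold (log2 2.78 ± 0.48) and 3.42-fold (1.77 ± 0.30). The interferon list had 6 of 18 higher (14 adjusted over the list alone; median 1.22, adjusted p = 2.92e-09, and adjusted p = 0.0676 with an estimated correlation), with IFIT2, which binds foreign RNA, 6.31-fold higher (2.66 ± 0.50). The NF-kB list had 6 of 17 higher (13 adjusted over the list alone; median 1.18, adjusted p = 3.97e-10, and adjusted p = 0.0741 with an estimated correlation), with the adhesion molecule ICAM1 4.74-fold higher (2.25 ± 0.44). The ER stress list had 7 of 20 higher (9 higher and 1 lower adjusted over the list alone; median 0.66, adjusted p = 6.72e-05, and adjusted p = 0.149 with an estimated correlation). ATF3 and PPP1R15A, targets of the integrated stress response, rose 3.42-fold (1.77 ± 0.37) and 3.23-fold (1.69 ± 0.33). ICAM1, ATF3 and PPP1R15A were not called without untreated array 1, and GDF15 and IFIT2 were lower on CD44lo array 2 than on the other 3. With the hybridisation controls as a covariate, IFIT2, ATF3 and PPP1R15A were not called.

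Several lists moved in CD44lo cells after epirubicin without a called member to match. On CD44lo array 2 the mean of the DNA replication list was 0.06 and that of the cholesterol list -0.09. The other CD44lo arrays had -0.72 to -0.48 and -0.63 to -0.44. DNA replication genes had 22 of 24 negative changes and 0 called (0 over the list alone; median -0.46, adjusted p = 0.000553, and adjusted p = 0.476 with an estimated correlation). Oxidative phosphorylation genes had 21 of 24 negative changes and 0 called (0 over the list alone; median -0.24, adjusted p = 0.00235, and adjusted p = 0.446 with an estimated correlation). Of the cholesterol genes, 12 of 13 had negative changes (median -0.33, adjusted p = 0.00485, and adjusted p = 0.356 with an estimated correlation), 0 of them called, and SC5D alone was called, higher by 1.63-fold (1 higher and 4 lower over the list alone). SC5D lost its call without any 1 array, and with the hybridisation controls as a covariate. The cholesterol list did not pass without untreated array 1 (adjusted p = 0.0919, median -0.21), and its median was -0.61 without untreated array 3. The stromal and endothelial list passed with 1 of 3 called, CDH5, an endothelial cadherin (3.74-fold, log2 1.90 ± 0.25, signal 139 ± 28.5 against 33.4 ± 2.58; 1 over the list alone; adjusted p = 0.0374, and adjusted p = 0.27 with an estimated correlation; 0.0759 with quantile normalization, 0.0545 without CD44lo array 2 and 0.0706 without CD44lo array 3). Other lists did not pass. The p53 target list had 2 of 20 higher (3 over the list alone; adjusted p = 0.0747), stem cell associated 2 of 19 (4 over the list alone; 0.0709), basal 0 of 11 (2 higher and 1 lower over the list alone; 0.0709), immune 1 of 5 (1; 0.36), epithelial 1 of 24 (1; 0.709), mitosis 0 of 25 (0; 0.635), mesenchymal 1 lower of 11 (1; 0.43) and hypoxia 2 lower of 24 (1 higher and 2 lower; 0.709).

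Among the called genes that were lower in CD44lo cells after epirubicin, SIGLEC6, a sialic acid receptor, was 4.70-fold lower (log2 -2.23 ± 0.50) and TGFB3, a transforming growth factor, 3.53-fold lower (-1.82 ± 0.43). The metallothionein MT1H, which binds zinc and copper, was 3.58-fold lower (-1.84 ± 0.45). THRSP, a lipogenic protein, was 3.64-fold lower (-1.87 ± 0.41). Adjusted p was 0.0159 to 0.0283, and each of these 4 calls ended without untreated array 1, without untreated array 2 and with the hybridisation controls as a covariate. Those of SIGLEC6, TGFB3 and MT1H also ended without CD44lo array 1 or 3, those of TGFB3, MT1H and THRSP without CD44lo array 4, and that of MT1H without untreated array 3.

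CD44hi cells after epirubicin against untreated cells had genes of the same 4 lists higher, and the basal list passed as well; with an estimated correlation the ER stress and basal lists did not pass. SERPINA3 rose 29.8-fold (log2 4.90 ± 0.47), LBP 18.3-fold (4.19 ± 0.57), and TFPI2, a protease inhibitor, 17.7-fold (4.15 ± 0.48), from a signal of 41.4 ± 12.6 to 957 ± 640. GDF15 rose 16.6-fold (4.05 ± 0.63). ACTA2 rose 10.8-fold (3.43 ± 0.39) and CAV1 5.25-fold (2.39 ± 0.37). FN1 rose 5.03-fold (2.33 ± 0.46), and S100A4, a calcium-binding protein, fell 2.21-fold (-1.15 ± 0.13). Adjusted p for these genes was 1.49e-05 to 0.00411, and FN1 alone among them was not called without untreated array 1. With the hybridisation controls as a covariate FN1 and GDF15 were not called.

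Here 823 genes were called, 593 higher and 230 lower, and 500 changed at least 2-fold. The count was 213 without untreated array 1, 277 without untreated array 2, 544 without untreated array 3 and 444 without CD44hi array 4. It was 461 without the epirubicin arrays numbered 4, 1279 without the sorted arrays numbered 2, 1348 in a fit of the compared groups alone, and 99 with the hybridisation controls as a covariate, in which the median size of change of the 823 genes went from 1.14 to 0.85 and their median standard error from 0.27 to 0.34. Of 57 named calls, 24 held whichever array was left out.

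Antigen presentation genes were called higher for 11 of 16 in CD44hi cells after epirubicin (14 adjusted over the list alone; median 1.42, adjusted p = 8.08e-13, and adjusted p = 0.0466 with an estimated correlation), with PSMB9 9.14-fold (log2 3.19 ± 0.48) and HLA-C, a class I molecule, 3.87-fold higher (1.95 ± 0.34). The NF-kB list had 13 of 17 higher (14 adjusted over the list alone; median 1.72, adjusted p = 9.07e-12, and adjusted p = 0.0466 with an estimated correlation). ICAM1 rose 6.10-fold (2.61 ± 0.44), and the cytokine IL6 rose 5.71-fold (2.51 ± 0.72) from a signal of 0.63 ± 0.21, a call (adjusted p = 0.04) that ended without any single array other than CD44hi array 1. The interferon list had 8 of 18 higher (13 adjusted over the list alone; median 1.29, adjusted p = 1.97e-09, and adjusted p = 0.0466 with an estimated correlation), with IFIT2 5.99-fold higher (2.58 ± 0.50). Of 20 ER stress genes, 7 rose (8 higher and 1 lower adjusted over the list alone; median 0.62, adjusted p = 0.000315, and adjusted p = 0.113 with an estimated correlation), with ATF3 4.29-fold higher (2.10 ± 0.37). The mean of the ER stress list was 0.95 on CD44hi array 4, the array with the highest ACTB ratio, against 0.49 to 0.56 on the other 3. With the hybridisation controls as a covariate, PSMB9, HLA-C, ICAM1, IL6, IFIT2 and ATF3 were not called.

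Of the basal list, 4 of 11 genes rose in CD44hi cells after epirubicin (6 higher and 1 lower adjusted over the list alone; median 0.91, adjusted p = 0.000315, and adjusted p = 0.0768 with an estimated correlation), among them LAMB3 (3.88-fold, log2 1.96 ± 0.36) and CAV2, a caveolin (4.01-fold, 2.00 ± 0.38). The stem cell associated list had 5 of 19 higher over all genes and over the list alone (median 0.24, adjusted p = 0.00652, and adjusted p = 0.113 with an estimated correlation), with ALDH1A3, a retinaldehyde dehydrogenase, 1.91-fold higher (0.94 ± 0.17), and a median of 0.43 without untreated array 2. DNA replication genes had 23 of 24 negative changes and 0 called (0 over the list alone; median -0.49, adjusted p = 0.000955, and adjusted p = 0.471 with an estimated correlation), and oxidative phosphorylation genes 20 of 24 negative and 0 called (0 over the list alone; median -0.34, adjusted p = 0.00623, and adjusted p = 0.471 with an estimated correlation). Cholesterol genes had 12 of 13 negative changes (median -0.55, adjusted p = 0.00952, and adjusted p = 0.353 with an estimated correlation), and the single called member, SC5D, was 1.77-fold higher (0.83 ± 0.19; 1 higher and 2 lower over the list alone). The cholesterol list did not pass without untreated array 1 (adjusted p = 0.106). On CD44hi array 2 the mean of the DNA replication list was 0.02 and that of the cholesterol list 0.01. The other CD44hi arrays had -1.01 to -0.31 and -0.84 to -0.51. CDH5 rose 5.13-fold (2.36 ± 0.25), 1 of 3 stromal and endothelial markers (1 over the list alone; adjusted p = 0.0113, and adjusted p = 0.113 with an estimated correlation). ITGAM, an integrin of myeloid cells, rose 2.66-fold (1.41 ± 0.35, signal 21.1 ± 2.15), 1 of 5 immune markers (1 over the list alone; adjusted p = 0.0475, and adjusted p = 0.113 with an estimated correlation). That list did not pass with quantile normalization (0.12) or without untreated array 2 or 3 or CD44hi array 2 or 4 (0.0522 to 0.0826), and ALDH1A3, ITGAM and SC5D were not called with the hybridisation controls as a covariate.

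The p53 target list did not pass in CD44hi cells after epirubicin, with 3 of 20 higher (8 adjusted over the list alone; adjusted p = 0.0538), among them TP53INP1, a p53-induced nuclear protein (3.26-fold, log2 1.70 ± 0.39). Neither did the lists of mitosis (0 of 25, and 0 over the list alone; 0.132), mesenchymal genes (2 higher and 1 lower of 11, 3 and 1 over the list alone; 0.0862), hypoxia (2 higher and 2 lower of 24, the same over the list alone; 0.763) and epithelial genes (2 higher and 1 lower of 24, 3 and 4 over the list alone; 0.873). Within the hypoxia list ADM was 3.40-fold higher (1.77 ± 0.45) and PDK1, which restrains pyruvate dehydrogenase, 2.16-fold lower (-1.11 ± 0.17). Of 2 other probe sets of PDK1, 1 changed the other way, though not at an unadjusted limma p under 0.05. Among the largest falls, THRSP was 6.33-fold (-2.66 ± 0.41), TGFB3 4.43-fold (-2.15 ± 0.43) and COL5A2, a fibrillar collagen, 7.34-fold lower (-2.88 ± 0.64). ADM, TP53INP1 and COL5A2 were not called without untreated array 1, nor were ADM and TP53INP1 without untreated array 2, nor ADM without CD44hi array 4. With the hybridisation controls as a covariate ADM, TP53INP1, COL5A2 and TGFB3 were not called.

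**Figure D3:**
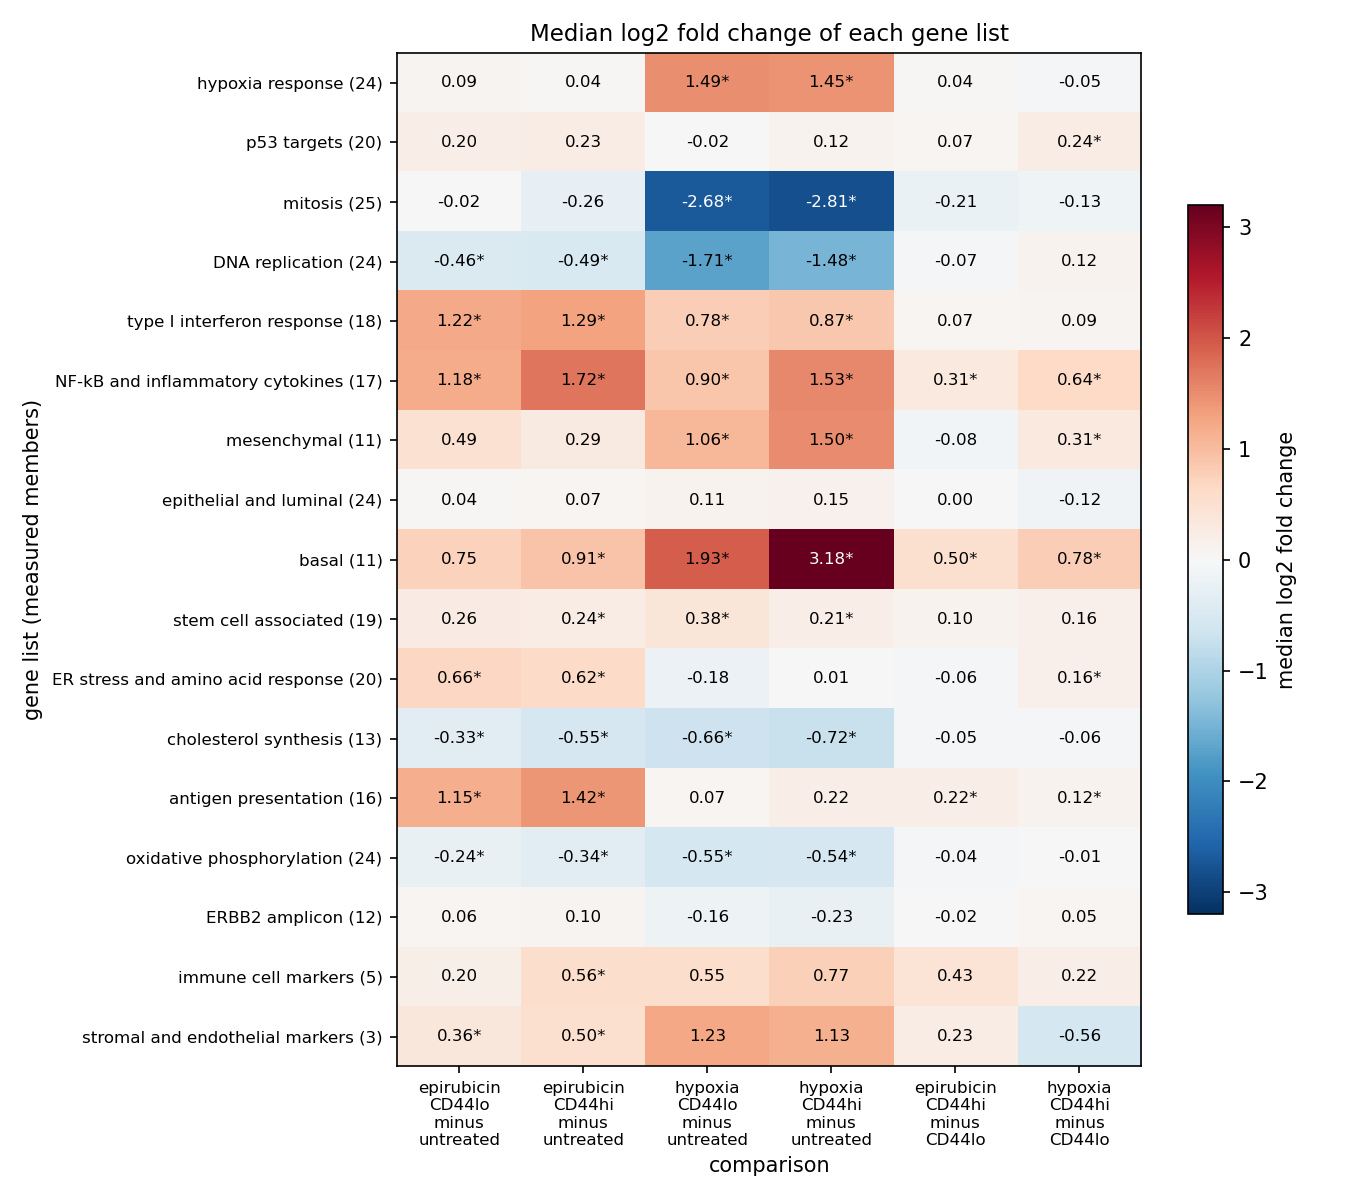
Median log2 fold change of the measured genes of each of the 17 lists (number of measured genes in brackets) in 6 comparisons, as colour and number. An asterisk marks an adjusted camera p under 0.05 at an inter-gene correlation of 0.01. The medians range from -2.81 for mitosis to 3.18 for the basal list, both in CD44hi cells after hypoxia against untreated.

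Between CD44hi and CD44lo cells sorted after epirubicin limma called 3 genes, 2 actins and a transcript antisense to 1 of them, and 10 with the replicate number as a block. ACTA2, the smooth muscle actin, was 6.63-fold higher in CD44hi cells (log2 2.73 ± 0.36, adjusted p = 0.00286), with a mean signal of 228 ± 151 against 24.9 ± 5.88 and 13.8 ± 4.25 in untreated cells. ACTA1, the skeletal muscle actin, was 6.27-fold higher (2.65 ± 0.43, adjusted p = 0.0264), with 122 ± 88.9 against 12.8 ± 4.96 and 7.13 ± 0.60 in untreated cells. The third called gene, named although outside the rule and chosen after its values were seen, was ACTA2-AS1, a transcript antisense to ACTA2 (3.21-fold, 1.68, adjusted p = 0.0489). Its signal and that of ACTA2 cannot be told apart where the genes overlap.

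These 3 genes, all higher, were the called genes of 12917 in limma, and 312 genes had an unadjusted p under 0.05 where 646 would be expected by chance. The count was 1 without CD44lo array 2, CD44hi array 2 or CD44hi array 4, and 0 without all sorted arrays numbered 2, in a fit of the compared groups alone and when all probe sets of a gene were averaged. ACTA2 was called whichever single array was left out, and ACTA1 was not called without CD44lo array 2, 3 or 4 or CD44hi array 2 or 4.

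By the correlations of these same arrays, replicate numbers paired the CD44lo and CD44hi samples after epirubicin, with number 3 at r = 0.114 just over the bound of 0.1. The labels do not state such pairs. With the number as a block 10 genes were called, all higher in CD44hi cells. They were ACTA2 (adjusted p = 0.00106), ACTA1 (0.00353), CD44 (5.94-fold, log2 2.57 ± 0.37, adjusted p = 0.0115), IGFBP3 (log2 2.07 ± 0.29, 0.00847), MYL9 (3.91-fold, 1.97 ± 0.23, 0.00241), ACTA2-AS1 (0.013), HEG1 (2.52-fold, 1.34 ± 0.20, 0.0115), TGFB2 (2.17-fold, 1.12 ± 0.19, 0.0367), BASP1 (1.84-fold, 0.88 ± 0.14, 0.0175) and TPM1 (1.46-fold, 0.55 ± 0.09, 0.0231). MYL9 and TPM1, a tropomyosin, are parts of the contractile apparatus, and TGFB2 is a transforming growth factor. Genes of this group outside the naming rule were chosen after their values were seen.

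Of the lists, basal genes had 10 of 11 positive changes in CD44hi over CD44lo cells after epirubicin, with 0 called (2 adjusted over the list alone; median 0.50, adjusted p = 1.39e-06, and adjusted p = 0.0467 with an estimated correlation; 1.05e-05 with the block). The NF-kB list had 14 of 17 positive changes, with 0 called (0 over the list alone; median 0.31, adjusted p = 0.00258, and adjusted p = 0.432 with an estimated correlation; 0.00024 with the block). The antigen presentation list had 15 of 16 positive changes, with 0 called (0 over the list alone; median 0.22, adjusted p = 0.00174, and adjusted p = 0.432 with an estimated correlation; 0.00024 with the block). Without CD44hi array 2 the basal list passed with a median of 0.32 (adjusted p = 0.00603). The NF-kB list did not pass without CD44lo array 4 or CD44hi array 2 (adjusted p = 0.147 and 0.118; medians 0.21 and 0.26). The antigen presentation list did not pass without CD44lo array 2 or CD44hi array 4 (0.257 and 0.239; medians 0.07 and 0.12), and its median was 0.36 without CD44lo array 4 and 0.37 without CD44hi array 2. The stem cell associated list, with 14 of 19 positive changes and 0 called (0 over the list alone), missed the threshold (adjusted p = 0.053) and passed with the block (0.0115). Mitosis genes had 24 of 25 negative changes and did not pass (median -0.21, adjusted p = 0.0708; 0.137 with the block). The mesenchymal list held 1 called member of 11, ACTA2 (1 over the list alone; adjusted p = 0.056), and all other lists had 0 called members.

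Between CD44hi and CD44lo cells sorted after hypoxia limma called 0 genes, with 886 at an unadjusted p under 0.05. With the replicate number as a block it called 100, among them CD44 (7.46-fold, adjusted p = 0.00287), although not every pair of equal number correlated. Without the block 6 of 17 lists passed, 0 of them with an estimated correlation. Basal genes had 10 of 11 positive changes in CD44hi over CD44lo cells (0 called, 1 adjusted over the list alone; median 0.78, adjusted p = 3.8e-05, and adjusted p = 0.133 with an estimated correlation). NF-kB and cytokine genes had 15 of 17 positive changes (0 called, 2 over the list alone; median 0.64, adjusted p = 1.04e-05, and adjusted p = 0.279 with an estimated correlation). Mesenchymal genes had 10 of 11 positive changes (0 called, 2 over the list alone; median 0.31, adjusted p = 0.00222, and adjusted p = 0.313 with an estimated correlation). The lists of p53 targets (13 of 20 positive, median 0.24), ER stress (15 of 20, median 0.16) and antigen presentation (10 of 16, median 0.12) passed with adjusted p of 0.0296, 0.0493 and 0.0493, and with 0 members called over all genes and over each list alone. For these the adjusted p was 0.279, 0.534 and 0.607 with an estimated correlation, and the ER stress and antigen presentation lists did not pass with quantile normalization (0.0663 and 0.0551). The p53 target and mesenchymal lists did not pass without CD44lo array 2 (adjusted p = 0.058 and 0.0741) or CD44hi array 4 (0.112 and 0.0808). The ER stress list did not pass without CD44lo array 2 or 4 or CD44hi array 1, 3 or 4 (0.073 to 0.393), and the antigen presentation list did not without CD44lo array 2 or 3 or CD44hi array 3 or 4 (0.0854 to 0.474). Without any single array the basal and NF-kB lists passed, but the basal median was 0.50 without CD44lo array 3 and the NF-kB median 0.34 without CD44lo array 2 and 0.35 without CD44hi array 4. The median of the mesenchymal list was 0.49 without CD44lo array 1, 0.17 without CD44lo array 3 and 0.59 without CD44hi array 3. That of the p53 target list was 0.05 without CD44lo array 1 and 0.12 without CD44hi array 1. The medians of the ER stress and antigen presentation lists, 0.16 and 0.12 with all arrays, ranged from 0.05 to 0.28 and from 0.03 to 0.26 without single arrays.

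The 886 genes at an unadjusted p under 0.05 compare with 646 expected by chance. Without CD44lo array 4, 6 genes were called, all higher in CD44hi cells. CD44lo arrays after hypoxia were themselves spread widely in CD44, from 20.5 on array 2 to 456 on array 4, where untreated cells had 52.4 to 78.8.

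Whether the CD44hi and CD44lo cells differ in another way after epirubicin than after hypoxia was tested as the difference of the CD44 effects. Limma called 0 genes, with 264 at an unadjusted p under 0.05, and 0 of 17 lists passed, the lowest adjusted p being 0.118 for stromal and endothelial markers. The difference was -0.33 ± 0.91 for CD44, 0.23 ± 0.26 for CD24 and -0.07 ± 0.22 for ERBB2 on the log2 scale. Across genes, the CD44 effects after epirubicin and after hypoxia correlated at r = 0.276 (Spearman's rho 0.201), and 56.4% of genes changed in the same direction. With 3 and 0 genes called by limma without the block, a gene called in both was not possible. With the replicate block 4 genes were called in both. Permuting the CD44 labels of the hypoxia arrays gave a two-sided exact p of 0.0286, the smallest possible, and permuting those of the epirubicin arrays gave 0.229, or 0.114 and 0.305 after adjustment over 4 such tests. Exchanging the epirubicin labels only within pairs of equal number gave 0.25 over 16 arrangements, where 0.125 is the smallest possible. The correlation was 0.146 without the arrays numbered 2, 0.179 without CD44lo array 1 and 0.138 without CD44hi array 2 after epirubicin, 0.172 without CD44lo array 2 after hypoxia, 0.171 with no filter on low signal and 0.423 with the stricter filter.

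Genes called against untreated after both epirubicin and hypoxia were counted within each sort. All treated cells were sorted, so these counts do not separate what the treatments share from the sorting. In CD44hi cells, 339 genes were called higher after both treatments where 75.9 would be expected by chance (Fisher's exact p = 1.47e-155), 121 were lower after both (32.3 expected, p = 2.81e-44) and 15 moved in opposite directions (113 expected). SERPINA3, CAV1, LAMB3, ICAM1 and ACTA2 were among the genes higher after both. In CD44lo cells, 128 were higher after both (31.1 expected, Fisher's exact p = 2.5e-49), 19 lower after both (8.20 expected, Fisher's exact p = 0.000477) and 7 opposite (41.5 expected). Of the 460 genes called in the same direction in CD44hi cells, the count became 122 without untreated array 1, 151 without untreated array 2 and 254 without epirubicin CD44hi array 4. The 147 in CD44lo cells became 23 without untreated array 1, 34 without untreated array 2, 78, 74 and 80.0 without epirubicin CD44lo arrays 1, 3 and 4, and 263 without hypoxia CD44lo array 2. With the hybridisation controls as a covariate the overlap of treated minus untreated between epirubicin and hypoxia was 73 genes in CD44hi and 47 in CD44lo cells. Across all genes the changes correlated at r = 0.617 in CD44hi cells (rho 0.614) and 0.518 in CD44lo cells (rho 0.558). Simulated unchanged groups that shared the 3 untreated arrays gave r = 0.572 in either sort and 0 genes called in both. With no gene changed in them, that 0 was nearly fixed in advance and is no measure of chance overlap. The expected counts and Fisher's test do not allow for the shared untreated arrays either. The covariance exceeded the simulated one by 0.248 in CD44hi cells and by 0.138 in CD44lo cells. Part of the excess may still come from the shared untreated arrays, which are too few to be divided between the treatments.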

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

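Chosen only after the results were seen were the test of array scaling, the tests of shared actin probe sets, and the fits without the arrays numbered 4, without the arrays numbered 2 and with the hybridisation controls.

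In groups of 4 arrays, an array lying far from the other 3 was looked for by Dixon's ratio, the gap to the nearest array over the range of the group, against its 95% limit. Chance puts about 1 in 20 groups over that limit, so 31.4 of 628 groups would be expected, and 29 were found. Signals are given as log2(signal + 4.2), and lists as the mean difference from untreated. After hypoxia, arrays numbered 2 had the lowest hypoxia list means, 1.05 against 2.09 to 2.26 in CD44lo cells (ratio 0.857) and 1.14 against 2.00 to 2.15 in CD44hi cells (0.852). ADM was lowest on CD44lo array 2 (8.53 against 10.45 to 10.79; 0.849) and PDK1 and IFI44 on CD44hi array 2 (8.14 against 8.61 to 8.68; 0.873, and 3.55 against 4.65 to 4.79; 0.889). On CD44hi array 2 ACTA2 (10.17 against 9.58 to 9.64; 0.892), SRARP (5.34 against 2.74 to 2.93; 0.93) and EBP (9.18 against 8.51 to 8.62; 0.846) were highest. Other arrays after hypoxia stood apart for CHAC1 (CD44lo array 1, 4.26 against 5.17 to 5.27; 0.904), ISG15 (CD44lo array 1, 3.72 against 6.99 to 7.49; 0.866), INSIG1 (CD44lo array 1, 7.43 against 6.24 to 6.33; 0.924), CAV2 (CD44lo array 3, 5.45 against 6.78 to 7.00; 0.853), HLA-G (CD44hi array 4, 7.79 against 7.31 to 7.35; 0.903) and the ratio of 3' to 5' signal of GAPDH (CD44lo array 4, 0.91 against 0.853 to 0.859; 0.904).

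After epirubicin, CD44lo array 2 was lowest for GDF15 (7.11 against 8.86 to 9.07; ratio 0.891), HLA-B (7.09 against 8.26 to 8.47; 0.851) and IFIT2 (4.93 against 5.69 to 5.85; 0.831) and highest for EBP (9.89 against 9.34 to 9.37; 0.949). CD44lo array 4 was lowest for the mitosis list (-0.32 against 0.06 to 0.09; 0.946), MUC1 (6.38 against 8.48 to 8.77; 0.881) and SDHD (9.57 against 10.06 to 10.10; 0.917). CD44hi array 4 was lowest for KIF20A (6.66 against 8.13 to 8.41; 0.838), TPX2 (8.04 against 9.29 to 9.52; 0.841), MUC1 (5.92 against 8.57 to 8.87; 0.898) and SDHD (9.27 against 9.90 to 10.00; 0.871), and highest for IFI44 (5.60 against 4.32 to 4.44; 0.908) and the ER stress list (0.95 against 0.49 to 0.56; 0.849). CD44hi array 1 was highest for COL5A1 (above the other arrays at 5.93 to 5.99; 0.893) and SPDEF (7.16 against 6.40 to 6.48; 0.897).

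Probe sets with no gene named were outside the comparisons of the report. Of 4450 that passed the filter, limma called 14 in CD44lo cells and 59 in CD44hi cells after epirubicin, and 340 in CD44lo cells and 497 in CD44hi cells after hypoxia, each against untreated.

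More genes were called higher than lower in CD44hi cells after epirubicin, 72.1% of 823. Tested as the whole cause were array scaling, RNA quality of the arrays numbered 4 and the level of the hybridisation controls. Each called for at most 60% higher once corrected. The share was 73.2% of 691 genes with quantile normalization, 79.8% of 461 without the arrays numbered 4 and 85.9% of 99 with the hybridisation controls as a covariate. The shares with quantile normalization and without the arrays numbered 4 argue against array scaling and against those arrays as the whole cause. RNA quality on the other arrays was not corrected. CD44hi arrays 1 and 3 had ACTB ratios of 1.39 and 1.54 and array 2 had 1.24, against a mean of 1.24 ± 0.03 in untreated cells. The covariate ended most calls, because the median size of change fell from 1.14 to 0.85 and the median standard error rose from 0.27 to 0.34. The share among the calls that were left thus cannot decide on the level of the controls as the cause. Of the covariate's variance, 46.8% lay between the groups, so the part of a change that follows the controls stays open.

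On the second principal component, with 15.4% of the variance and the untreated arrays at -40.0 to -21.5, the arrays numbered 2 were the lowest of their group in all 4 groups (-2.77 and 8.41 in CD44lo and CD44hi cells after epirubicin, -40.5 and -27.1 after hypoxia). On the first they lay closest to the untreated arrays after hypoxia only. If they had been processed together with those arrays, their deviations over 425 genes with a limma p above 0.5 against untreated in all 4 groups would correlate between the treatments. The mean r was 0.176, against 0.207 for the arrays numbered 1, too low to show it and too high to exclude it. Genes that such processing set apart from the untreated arrays would be left out by that choice, which weakens the test. If their cells had responded more weakly, the slope of their changes on those of the other arrays would be under 0.8 in all 4 groups and the lowest of each group; the slopes were 0.618, 0.831, 0.534 and 0.65, and in CD44hi cells after epirubicin array 1 had a lower one, 0.761. A weaker response and a shared processing cannot be told apart here, as the 0.831 lay between the bounds set for either outcome.

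Actins and other contractile genes were among the largest rises in CD44hi cells after hypoxia against untreated. Signal shared between actin probe sets, as the whole cause, would leave other contractile genes unmoved. Of those measured, 14 of 15 were called higher in CD44hi cells after hypoxia against untreated. Stromal cells would bring collagens at high levels, but the highest mean signal of COL1A1, COL1A2, COL3A1, DCN and LUM there was 36.4 (COL1A1), against 872 for ACTA2. For this comparison these values argue against stromal cells, and against shared actin signal as the whole cause. They do not bear on signal shared among the actins themselves. For CD44hi against CD44lo cells, 0 of the 15 genes were called in limma without the block, but 14 of 15 changes were positive after epirubicin (camera p = 0.0164 with an estimated correlation and the replicate block; 0.0304 without MYL9 and TPM1, seen before the list was made) and 15 of 15 after hypoxia (0.00272, and 0.0029 without those 2 genes). Without any single array p was at most 0.00878 and 0.0108, without the block. These values argue against shared actin signal as the whole cause there too, though how much of each actin's own change is shared signal was not measured. A contractile program within the cancer cells may be a hypothesis, found and tested on the same data.

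Other divisions of the same arrays into groups of equal size were also fitted. Against untreated, the real division called more genes than any other in 3 comparisons, 1 of 35 divisions being as large in each. These were CD44lo after epirubicin (360 genes, highest other 123), CD44hi after epirubicin (823, highest other 273) and CD44hi after hypoxia (3467, highest other 2919). A share of 1 in 35 is the smallest this count can give and was not adjusted over the 7 comparisons. It argues against chance without excluding it. For CD44lo after hypoxia against untreated, 2 of 35 divisions were as large as the 2899 genes, so chance is not excluded by this count; the highest other, 3314 genes, joined CD44lo array 2 to the untreated arrays, a structure of the samples. Chance is not excluded for CD44hi against CD44lo after epirubicin (3 genes; 3 of 35 as large), where the highest other, 30 genes, set numbers 1 and 2 against 3 and 4, which points to a structure of the samples that follows the replicate number. Among the 8 divisions that part all 4 pairs of equal number, the real one alone called genes, and the others called 0 in limma. After hypoxia the same comparison (0 genes; 35 of 35 as large) had a highest other of 658, and the difference of the CD44 effects (0 genes; 100 of 100 as large) one of 969. With a real count of 0 these shares were fixed in advance and say nothing about chance. The division with 658 genes set CD44lo arrays 1, 2 and 3 and CD44hi array 2 against the other 4, and the one with 969 divided the hypoxia arrays in the same way. It differs from the sort by 1 array on each side, CD44lo array 4 (CD44 signal 456) and CD44hi array 2 (487), and puts both arrays numbered 2 on one side and both numbered 4 on the other, so it points to a structure of the samples that follows the sort in part and the number in part.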

How the results depend on the processing

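Leaving out single arrays from the list tests, the fits without the arrays numbered 4, without the arrays numbered 2 and with the hybridisation controls as a covariate, and most alternatives for the overlaps and for the correlation of the CD44 effects, were chosen only after the results were seen. None of the named calls and none of the list tests that passed changed direction; among list tests that did not pass, the direction turned in 9 with quantile normalization and in 8 with the block, all with adjusted p of 0.132 or more. Over all settings, 4255 checks of 233 named calls kept 3786 calls and lost 469. The largest numbers were lost with the covariate (73 of 233), without untreated array 1 (70 of 231) and without untreated array 2 (56 of 231), and the largest shares without epirubicin CD44lo arrays 1, 3 and 4 (15, 14 and 13 of 36) and CD44hi array 4 (21 of 59). For CD44hi against CD44lo after epirubicin, 3 genes became 1 with the doubled offset, without the arrays numbered 4 and with the covariate, 0 with the mean of all probe sets, in a fit of the compared groups alone and without the arrays numbered 2, and 10 with the replicate block. After hypoxia, where the pairs of equal number correlated at r = -0.04, 0.634, 0.279 and 0.541 and 6 of 8 arrays correlated best with their own number, 0 genes became 100 with the block, 65 higher and 35 lower. The overlap of CD44hi minus CD44lo between epirubicin and hypoxia, 0 genes, was 4 with the replicate block (ACTA1, ACTA2, BASP1 and CD44, all higher in CD44hi cells). It was 0 in limma under every other setting and without any single array. For independent calls 0.0774 would be expected with the block, but these calls are not independent. Both comparisons came from the same fit with the same standard error for each gene, CD44 was the sort marker, and actins can share signal. A fit of the compared groups alone gave 1186 genes for CD44lo and 1348 for CD44hi after epirubicin against untreated, in place of 360 and 823. Without the arrays numbered 4 these were 199 and 461, without those numbered 2 898 and 1279, and with the covariate 103 and 99. The block gave 893 for CD44lo after epirubicin and 1123 in place of 2899 for CD44lo after hypoxia, although the numbers of untreated and treated arrays do not pair. Leaving out single arrays gave 1 to 4 and 0 to 6 genes for CD44hi against CD44lo after epirubicin and after hypoxia. Against untreated the range was 66 to 432 for CD44lo and 213 to 890 for CD44hi after epirubicin, and 1628 to 3755 and 2316 to 3773 after hypoxia, each lowest without untreated array 1. Of 48 list tests that passed, 6 passed with an estimated correlation, which widens the error by construction; 44 kept their call with quantile normalization, 46 with the block and 35 whichever single array was left out. Other causes were not tested. The overlap of treated minus untreated between epirubicin and hypoxia was 460 genes in CD44hi and 147 in CD44lo cells. It was 364 to 480 and 125 to 172 with the alternatives of offset, filter, normalization, probe sets and trend, 629 and 208 with the block, 821 and 411 in a fit of the compared groups alone, 754 and 513 without the arrays numbered 2, 265 and 88 without the arrays numbered 4, and 73 and 47 with the covariate. Leaving out single arrays gave 122 to 526 and 23 to 263. Genes with signals near the offset of 4.2 have understated fold changes.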

Other observations

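The gene lists of this part and their tests were chosen only after the results were seen, so their counts and p-values are not independent of that choice. For the acute phase and metallothionein lists no test was run that left out members seen before. The test of a shared direction was not chosen after the results, apart from its arrangements within pairs.

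Cells after epirubicin had raised acute phase and complement genes. Of 10 such genes measured, 8 were called higher in CD44lo and 8 in CD44hi cells against untreated (median log2 change 2.50 and 2.86; camera p = 1.25e-14 and 2.11e-14, and 0.00105 and 0.00112 with an estimated correlation), while 3 and 5 were called after hypoxia (p = 0.126 and 0.0517). Complement factor CFB rose 5.79-fold in CD44lo and 6.42-fold in CD44hi cells after epirubicin, the protease C1S 4.74-fold and 6.82-fold, ceruloplasmin (CP) 5.55-fold and 7.72-fold, and PIGR, which carries antibodies across epithelia, 6.78-fold and 8.97-fold (adjusted p 0.00025 to 0.0115). C3 and ORM1 were not called. Metallothioneins went down after epirubicin, with 3 of 5 called lower in CD44lo and 4 of 5 in CD44hi cells (median -1.19 and -1.36; camera p = 2.01e-06 and 1.58e-05, and 0.0364 and 0.0542 with an estimated correlation) and 0 in limma after hypoxia (camera p = 0.534 and 0.774). MT2A had log2 changes of -1.19 ± 0.31 and -1.38 ± 0.31, and MT1X of -1.30 ± 0.31 and -1.36 ± 0.31. Whether these changes differ between the treatments was not tested.

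Contractile genes other than actins were put on a list after MYL9 and TPM1, 2 of its members, had been seen, so its tests are not independent of that choice. Between CD44hi and CD44lo cells limma called 0 of its 15 measured genes after either treatment. With the replicate block it called 2 after epirubicin and 3 after hypoxia. Of the 15, 14 had positive changes in CD44hi over CD44lo cells after epirubicin and 15 after hypoxia (median 0.35 and 0.42; camera p = 3.12e-13 and 6.44e-11, and 0.00119 and 0.00272 with an estimated correlation). Against untreated, 1 and 5 were called higher in CD44lo and CD44hi cells after epirubicin, and 11 and 14 after hypoxia. CALD1, which encodes caldesmon, rose 1.95-fold and 3.27-fold after epirubicin and 6.05-fold and 9.42-fold after hypoxia, and TAGLN, a smooth muscle protein, 3.81-fold and 9.07-fold after hypoxia.

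A further hypothesis was that CD44hi cells after either treatment differ from CD44lo cells in the direction in which the other treatment differs from untreated. The correlation across genes was 0.328 for the CD44 effect after epirubicin (two-sided exact permutation p = 0.171, highest other arrangement 0.411) and 0.229 for that after hypoxia (p = 0.543, highest other 0.505). Neither exceeded all other arrangements of the same arrays. After epirubicin the numbers pair the arrays by their correlations, though not by the labels, so arrangements that follow the number enter that comparison. With labels exchanged only within pairs, 0.328 was the highest of 16 arrangements (next 0.325, two-sided exact permutation p = 0.125, the smallest possible). These arrangements are too few to decide, and the hypothesis stays open there. After hypoxia the numbers do not pair every array, and among all 70 arrangements 0.229 did not stand out; with labels exchanged only within equal numbers 0.229 was the highest of 16 there as well (next 0.194; two-sided exact permutation p = 0.125), again too few to decide.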
